A study of Mus musculus with 12 samples.

How the data were processed

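Liver expression profiles of 12 mice were taken from the deposited value table of the series, which holds 45101 probe sets for each of 12 Affymetrix mouse arrays. Per the labels, total RNA was extracted from liver, copied into labelled cRNA and hybridised to 1 array per mouse. The values are log2 signals that the authors made with GCRMA, version 2.12.1 in R 2.7.0, per the submitters' processing notes. GCRMA corrects each probe's background from its sequence, normalizes the arrays to each other and summarises each probe set. The settings used for these steps are not given in the sources used here. The log2 scale was checked on the values, whose array medians lay between 2.32 and 2.34 and whose maxima lay between 16.7 and 17.0. Each array had 16494 to 16776 probe sets within 1e-06 of the lowest value, where GCRMA places probe sets without signal above background. A change measured from that floor depends on the background model, so linear folds are given only where both group means were at least 5. No pair of arrays held identical values (0 pairs), the lowest correlation between replicates was 0.996, and 0 values were missing. The number of arrays limits the precision.

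Groups came from the labels. WT vehicle (replicates 1, 2 and 3), WT CDDO-Im (2, 3 and 4), CKO vehicle (3, 4 and 5) and CKO CDDO-Im (2, 3 and 4) held 3 mice each, and all 12 arrays were used. The groups, the tests of genes and lists, the gene lists, the rule for naming genes and all but 2 of the alternatives below were chosen before the data were examined, and some tests of explanations in the closing section were not.

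Probe sets were named through the platform's annotation table, in which 34945 probe sets name 1 gene, 932 name several and 9173 are not named, and 64 control probe sets were left out. The Entrez identifiers of 34741 probe sets matched a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used only for names and for which genes neighbour each other. The brightest probe set over the 12 arrays stood for each of 18193 genes, and probe sets with several genes or none were not used. A gene was tested where at least 3 arrays exceeded a log2 value of 5, which left 8338 genes.

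A model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, so that all groups shared 1 estimate of the spread (8 residual and 2.32 prior degrees of freedom, median residual SD 0.163). It gave 5 comparisons between groups and the interaction of genotype and treatment. P-values were two-sided, adjusted by Benjamini-Hochberg over the 8338 genes, and called at an adjusted p under 0.05. Errors of changes are limma's standard errors and errors of group means are SDs over 3 mice. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, for 33 lists in 6 comparisons, and the 198 p-values were adjusted together. The 40 lists name 835 genes, of which 748 had a probe set of their own, and 7 lists had too few measured genes for camera. The lists came from general knowledge of liver biology and not from this study.

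The lists of defence and drug metabolism were glutathione synthesis and conjugation, quinone, aldehyde and peroxide detoxification, NADPH production and pentose phosphate pathway, glucuronidation and sulfation, carboxylesterases, hepatic transporters, cytochrome P450s of xenobiotic metabolism, and aryl hydrocarbon receptor targets. Those of metabolism were cholesterol synthesis and uptake, fatty acid and triglyceride synthesis, fatty acid oxidation and PPAR alpha targets, bile acid synthesis and transport and gluconeogenesis and glucose handling. Those of stress and inflammation were acute phase and inflammation, interferon response, heat shock and chaperones, unfolded protein response and amino acid stress, proteasome subunits and autophagy and ubiquitin adaptors. Further lists were Keap1-Nrf2 pathway regulators, metallothioneins and metal handling, heme synthesis and breakdown, cell cycle, p53 targets, early response transcription factors, circadian clock and male-biased and female-biased liver genes. The rest were pericentral and periportal hepatocyte genes and cell markers. The markers were those of hepatocytes, cholangiocytes, macrophages and Kupffer cells, neutrophils, lymphocytes, stellate cells and fibroblasts, endothelial cells, erythroid cells, pancreatic acinar cells and adipose tissue.

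Genes were named by rule. For each comparison these were the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap (not asked of the interaction), leaving out symbols of predicted genes and clones. For each list and comparison they were the 2 called members with the largest rise and the 2 with the largest fall or, where none was called, the member with the largest change. Keap1, Nfe2l2, Nqo1, Gclc, Gclm, Hmox1 and Txnrd1 were always named, and a gene named in 1 comparison was open to naming in the others.

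The overlap of the genetic and the pharmacologic response was set beside 100 simulated draws in which both groups were unchanged and shared the controls. Bootstrap intervals used 10000 resamples of genes, not of mice, so they do not measure the spread between animals. Alternatives were no filter on low values, a stricter filter at 7, quantile normalization, median centring, a trended and robust variance prior and array weights. Others were only the arrays of the 2 groups compared, every probe set tested, only probe sets with plain _at names, a minimum fold of 1.5, the replicate number as a block, each array left out in turn, and the estimated inter-gene correlation. Leaving out WT vehicle replicate 1 and CKO vehicle replicate 3 together, and leaving out the 421 genes with a value repeated within 0.001 on at least 6 arrays, were added after the data were seen. The test was tested on simulated data with the residual spread of each gene and changes set in the CKO vehicle group (8338 genes, 20 draws). There 56.0% of genes changed 1.5-fold, 83.2% of those changed 2-fold and 96.0% of those changed 4-fold were called, and 4.78% of the calls were false. The simulated noise was independent between genes and had no floor, unlike the arrays, so these shares need not hold for the real data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.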

Results

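Gene expression was measured in liver RNA from 12 male mice, 9 weeks old and on a C57BL/6J background, with 1 Affymetrix mouse array per liver. The mice formed 4 groups of 3, made by crossing genotype with treatment. Conditional Keap1 knockout mice (CKO) carried Albumin-Cre with a floxed and a null Keap1 allele, so that Keap1, the adaptor that targets the transcription factor Nrf2 for degradation, was deleted in hepatocytes. Their genetic controls (WT) carried Albumin-Cre with a floxed and a wild-type allele. Cre can delete the floxed allele of these controls too, so WT hepatocytes may keep only their wild-type allele. The null allele of CKO mice is also present outside hepatocytes. WT is therefore used here as a label for these controls and not for an unaltered Keap1 locus. Mice of each genotype received by gavage either vehicle or 30 umol/kg of CDDO-Im, a synthetic oleanane triterpenoid that activates Nrf2, and livers were taken 6 h later. Values were log2 signals of 45101 probe sets, with array medians of 2.32 to 2.34 and upper quartiles of 6.46 to 6.58. Between 16494 and 16776 probe sets per array sat at the lowest value (within 1e-06). Among the 18193 genes with a probe set of their own, 8338 passed the filter on low signal and were tested. The number of arrays limits the precision of every value.

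The targeted gene was examined first in every sample. Keap1 had 2 probe sets. In the order of the replicate numbers, the signals of the first were 8.17, 7.92 and 7.94 in WT vehicle livers and 8.46, 8.89 and 8.66 in WT CDDO-Im livers. They were 2.87, 2.74 and 2.76 in CKO vehicle livers and 3.31, 3.09 and 2.90 in CKO CDDO-Im livers, so that all 6 CKO arrays lay below all 6 WT arrays. The second gave 7.15, 7.48 and 6.58 in WT vehicle, 7.89, 8.08 and 7.76 in WT CDDO-Im, 6.51, 6.51 and 6.15 in CKO vehicle and 6.28, 6.29 and 6.45 in CKO CDDO-Im. The place of the 2 probe sets relative to the deleted part of the gene is not given in the sources used here, and a probe set outside that part checks nothing. The second probe set was the brighter over the 12 arrays and stood for the gene in the tests. With every probe set tested, the first differed by -5.23 (log2, adjusted p = 2.45e-08) between the vehicle groups and by -5.57 (adjusted p = 1.28e-08) between the drug groups. With the second Keap1 differed by -0.68 ± 0.20 (log2, SE) between the vehicle groups, which did not pass the test (limma adjusted p = 0.0712), and was lower in CKO CDDO-Im than in WT CDDO-Im livers by -1.57 ± 0.20 (adjusted p = 0.00553). In WT livers Keap1 rose with CDDO-Im by 0.84 ± 0.20 (adjusted p = 0.0478).

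**Figure D1:**
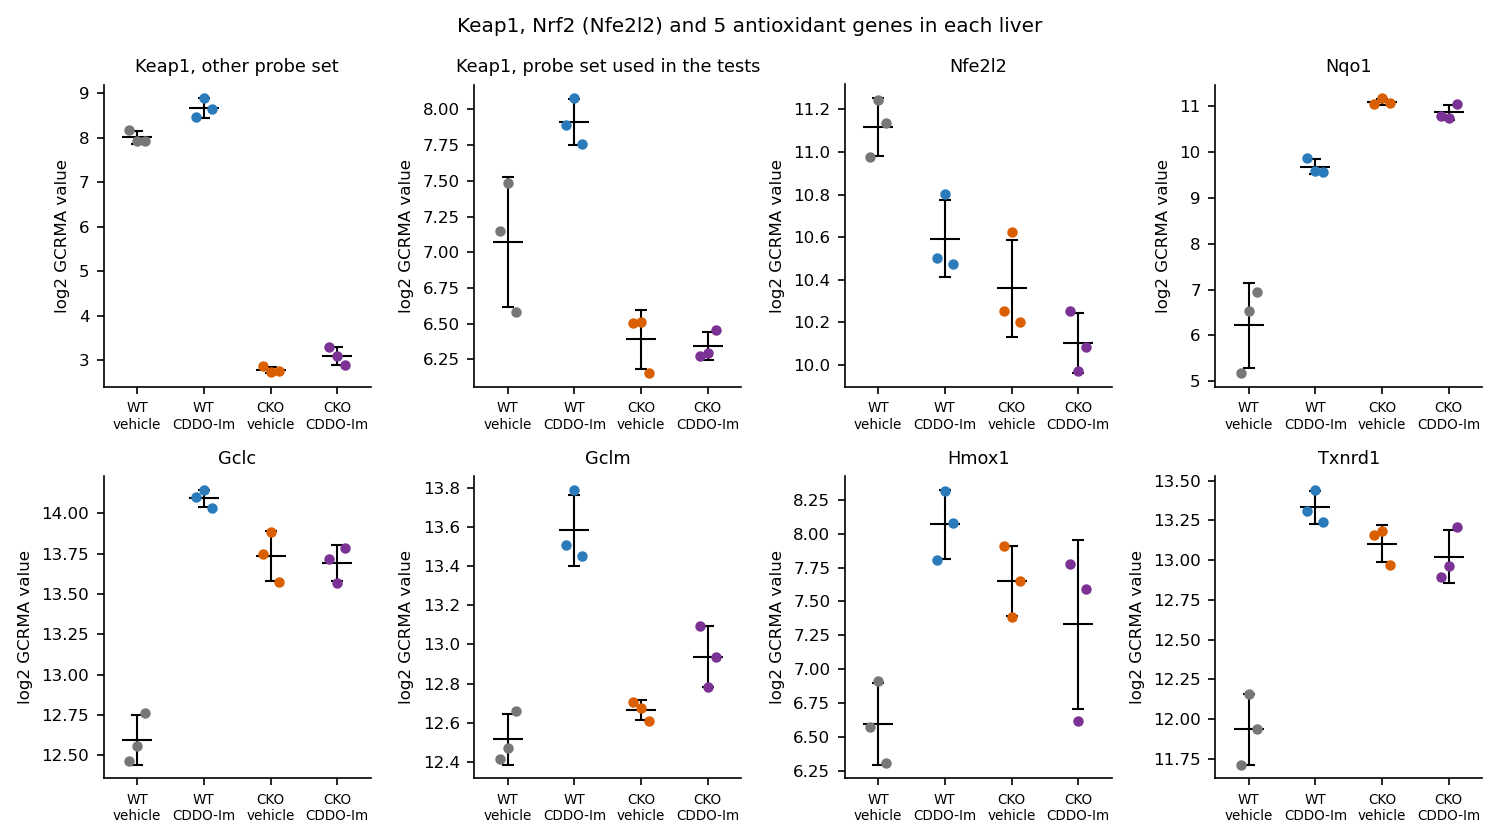
Log2 array signal (vertical axes) of Keap1, by each of its 2 probe sets, and of Nfe2l2 and Nrf2 target genes in each of the 12 livers, grouped along the horizontal axis by genotype and treatment, with points for livers and bars for the group mean ± SD (n = 3). Nqo1 rose from 6.22 ± 0.93 in WT vehicle to 9.67 ± 0.16 in WT CDDO-Im and stood at 11.08 ± 0.07 and 10.85 ± 0.17 in the CKO vehicle and CKO CDDO-Im groups.

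To define the hepatic genes that differed after genetic loss of Keap1, vehicle-treated CKO livers were compared with vehicle-treated WT livers. The largest rise was that of Cbr3, a carbonyl reductase, from 4.44 ± 2.36 to 14.55 ± 0.46 (log2 signal, mean ± SD, n = 3), and its relative Cbr1 rose 7.69-fold (adjusted p = 7.02e-06). Nqo1, a quinone reductase, rose 29.1-fold with a log2 change of 4.86 ± 0.35 (SE). The metallothioneins Mt2 and Mt1, which bind zinc and copper, rose 61.3-fold and 29.6-fold (log2 SE 0.55 and 0.46, adjusted p = 3.16e-04 and 3.18e-04), and the efflux transporter Abcc4 rose 54.3-fold (log2 SE 0.28, adjusted p = 3.92e-06). The largest fall was in Hsd3b5, a hydroxysteroid dehydrogenase of male mouse liver, from 13.06 ± 0.52 to 8.34 ± 1.87.

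By limma, 543 of the 8338 genes were called at an adjusted p under 0.05, of which 271 rose and 272 fell (320 and 280 with quantile normalization, 349 and 257 with median centring). All 543 had groups that did not overlap, as did 26.3% of the genes tested, where chance gives 10%. Of the called genes, 194 differed at least 2-fold. The 10 largest rises were those of Cbr3, Mt2, Abcc4, Mt1 and Nqo1 and of 5 more genes. Osbpl3 rose by 6.56 ± 0.43, Apela, which encodes a ligand of the apelin receptor, by 5.56 ± 0.26 and the urate transporter Slc22a12 by 5.25 ± 0.51 (log2 change ± SE). The annexin Anxa13 rose by 4.80 ± 0.57 and the glutamate transporter Slc1a1 by 4.27 ± 0.24. Osbpl3, Apela, Slc22a12, Anxa13, Slc1a1 and Cbr3 had WT vehicle means under 5, near the bottom of the scale, where the size of a change depends on the background model, so no linear fold is given. The falls after Hsd3b5 were -3.42 for Nxpe2, -3.17 for the fatty acid elongase Elovl3, -2.98 for the lipid droplet protein Pnpla3 and -2.98 for the interferon-induced Ifit1. They went on with -2.36 for Carmil1, -2.32 for Gas1, -2.30 for the interferon-induced GTPase Gbp6, -2.23 for Mn1 and -2.18 for Rtp4, with SE from 0.29 for Nxpe2 to 0.77 for Ifit1. The call for Ifit1 was lost in 9 of 12 fits without 1 array and that for Gbp6 in 4, with the highest adjusted p, 0.155 and 0.108, without CKO vehicle replicate 3. The count fell from 543 to 275 without CKO vehicle replicate 3 and to 302 without WT vehicle replicate 1.

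Glutathione synthesis and conjugation was called as higher in CKO livers. Of its 21 measured members 11 rose, 0 fell and 10 were not called, or 12 and 0 adjusted over the list alone (median log2 change 0.76, camera adjusted p = 1.72e-10, adjusted p = 0.137 with an estimated correlation). Gsta2 rose by 2.78 ± 0.18 and Gstm3 by 2.77 ± 0.33 (log2 change ± SE), both glutathione S-transferases. Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, rose 2.21-fold (adjusted p = 3.11e-04), while its modifier subunit Gclm differed by 0.15 ± 0.11 and was not called (adjusted p = 0.473). Quinone, aldehyde and peroxide detoxification was also called as higher. Of 23 members 6 rose, 1 fell and 16 were not called, or 13 and 2 adjusted over the list alone (median 0.33, camera adjusted p = 1.50e-07, adjusted p = 0.469 with an estimated correlation). Besides Cbr3, Nqo1 and Cbr1 the members that rose included the sulfiredoxin Srxn1, by 2.25 ± 0.25, the biliverdin reductase Blvrb, by 1.60 ± 0.11, and the thioredoxin reductase Txnrd1, by 1.17 ± 0.13, and the aldehyde oxidase Aox3 was the member that fell, at -1.05 ± 0.24. Hmox1, the heme oxygenase, differed by 1.05 ± 0.29 and did not pass the test (adjusted p = 0.0557, 0.048 with genes of repeated values left out). The call for Aox3 ended without CKO vehicle replicate 5 (adjusted p = 0.0905) and 3 other arrays. Nfe2l2, which encodes Nrf2 itself, was lower by -0.76 ± 0.14 (adjusted p = 0.0102).

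Lists of lipid synthesis were called as lower in CKO livers. Fatty acid and triglyceride synthesis had 24 members, of which 8 fell, 0 rose and 16 were not called, or 16 and 1 adjusted over the list alone (median -0.93, camera adjusted p = 1.42e-07, adjusted p = 0.469 with an estimated correlation). They included Pnpla3 and Elovl3, the fatty acid synthase Fasn at -1.56 ± 0.34 and the desaturase Fads1 at -1.35 ± 0.28 (log2 change ± SE), and 5 fell without WT vehicle replicate 1 or 2. Cholesterol synthesis and uptake had 2 of 19 members that fell and 17 not called, or 7 that fell adjusted over the list alone (median -0.76, camera adjusted p = 6.80e-06, adjusted p = 0.924 with an estimated correlation). These were Stard4, a sterol transport protein, at -1.60 ± 0.28, and Insig1, which retains the sterol sensor complex in the endoplasmic reticulum, at -1.34 ± 0.32. In WT vehicle replicate 1, 18 of the 19 cholesterol genes lay above the mean of the other 2 livers of its group, by a median of 1.05 (log2). Fatty acid oxidation and PPAR alpha targets had 4 of 29 members that fell and 25 not called, with the same count adjusted over the list alone (median -0.28, camera adjusted p = 0.00602, adjusted p = 0.938 with an estimated correlation), among them the nuclear receptor Ppara at -1.02 ± 0.26 and the lipid droplet protein Plin2 at -0.95 ± 0.14. In this list 1 fell without CKO vehicle replicate 3 or WT vehicle replicate 1 and 2 without CKO vehicle replicate 5 or WT vehicle replicate 2. The call for Insig1 was lost in 6 of 12 fits without 1 array and that for Ppara in 9, with the highest adjusted p, 0.111 and 0.137, without WT vehicle replicate 1. The oxidation list's call ended without WT vehicle replicate 2 (adjusted p = 0.153) and without CKO vehicle replicate 5 (adjusted p = 0.072).

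Interferon response genes were lower in CKO livers. Of 17 members 6 fell, 0 rose and 11 were not called, or 13 and 0 adjusted over the list alone (median -1.03, camera adjusted p = 1.47e-08, adjusted p = 0.61 with an estimated correlation). Besides Ifit1, Usp18, which restrains interferon signalling, was at -1.77 ± 0.29 and Irf9, a subunit of the interferon-activated transcription complex, at -1.40 ± 0.20 (log2 change ± SE), and 3 members fell without CKO vehicle replicate 3 or WT vehicle replicate 1 or 2. Male-biased liver genes were called as lower, with 5 of 17 members that fell and 12 not called, or 9 that fell adjusted over the list alone (median -0.87, camera adjusted p = 5.83e-04, adjusted p = 0.924 with an estimated correlation). Hsd3b5, Elovl3 and Slco1a1, an organic anion uptake transporter at -2.16 ± 0.32, were among them, and 7 of the 17 members were also in another list. The 3 CKO vehicle livers differed in this list, since 16 of its 17 members lay below the mean of the other 2 in replicate 4 (median -0.73) and 15 lay above it in replicate 3 (median 0.66). Female-biased liver genes had 1 of 8 members that fell, 0 that rose and a median of 0.92 (camera adjusted p = 0.594), and in CKO vehicle replicate 4 7 of 8 members lay above the mean of the other 2 livers (median over all 8 of 1.43). Cyp2b9 stood at 11.83 in this liver, against 2.49 and 4.66 in its group and 7.09, 2.47 and 5.10 in CKO CDDO-Im livers. The recorded sex was not checked on sex-linked genes.

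Camera called no shift in this comparison for the remaining 26 of the 33 lists it tested. Of the metabolic lists, NADPH production and the pentose phosphate pathway had 2 of 12 members that rose (Mthfd1l at 2.77 ± 0.32, Pgd at 1.09 ± 0.14, adjusted p = 0.298). Glucuronidation and sulfation had 4 that rose and 1 that fell of 21 (adjusted p = 0.0846) and hepatic transporters 4 and 2 of 21 (adjusted p = 0.214). Bile acid synthesis and transport had 2 that rose and 1 that fell of 18 (adjusted p = 0.941) and gluconeogenesis and glucose handling 1 and 0 of 17 (adjusted p = 0.507). Abcc5 at 3.96 ± 0.27 and Ugdh, which makes UDP-glucuronic acid, at 1.11 ± 0.13 were members of these that rose. Adjusted over the list alone, 8 rose and 2 fell in glucuronidation and sulfation and 7 rose and 5 fell among the transporters. Metallothioneins and metal handling had 4 of 15 members that rose, with a median of -0.12, a mean of 0.72 and a test pointing up (adjusted p = 0.222). Keap1-Nrf2 pathway regulators had 1 of 12 that rose, the small Maf protein Mafg at 0.51 ± 0.09, and 1 that fell, Nfe2l2 (adjusted p = 0.818). Heme synthesis and breakdown had 1 of 13 that rose (adjusted p = 0.624), p53 targets 1 of 12 (adjusted p = 0.292) and acute phase and inflammation 1 of 27 (adjusted p = 0.846). Early response transcription factors had 2 of 14 that rose and 2 that fell (adjusted p = 0.983) and the circadian clock 0 of 16 (adjusted p = 0.789). The acute phase member that rose was Orm3, at 2.49 ± 0.42, and CKO vehicle replicate 3 stood apart in Saa2, at 15.90 against 10.63 and 11.66, and in Lcn2, at 13.35 against 9.45 and 9.56.

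Markers of the liver's cell types gave few calls. Pericentral hepatocyte genes had 1 that rose and 1 that fell of 17 (camera adjusted p = 0.982), periportal hepatocyte genes 1 that fell of 17 (adjusted p = 0.539) and stellate cell and fibroblast markers 1 that fell of 13 (adjusted p = 0.68). Macrophage and Kupffer cell markers had 1 that rose of 13 (adjusted p = 0.157) and endothelial cell markers 1 that rose of 17 (adjusted p = 0.798). Marco, a macrophage scavenger receptor, rose by 2.30 ± 0.46 and Lyve1, a hyaluronan receptor of endothelium, by 2.24 ± 0.46. Reln, at -0.51 ± 0.12, was the stellate marker that fell. None of the measured macrophage, stellate and endothelial markers was in another list. Whole liver was measured, so the values do not tell which cells expressed these genes. Passing the filter on low signal does not show that a marker was expressed. A value repeated within 0.001 on at least 6 of the 12 arrays, as a background plateau gives, was found in 421 of the 8338 genes, among them the markers Epcam, Ighm, Hbb-b2, Ccr2 and Cdh5. The calls for Marco, Reln and Car3 were lost in 1, 6 and 6 of 12 fits without 1 array, with the highest adjusted p, 0.0658, 0.126 and 0.117, without CKO vehicle replicate 3. That for Lyve1 was lost in 3 (up to 0.0629, without WT vehicle replicate 1). A further 7 lists had too few measured members for camera. Aryl hydrocarbon receptor targets had 1 of 4 that rose, Nqo1, and adipose tissue markers 1 of 3 that fell, the carbonic anhydrase Car3 at -1.59 ± 0.37, or 2 that rose and 1 that fell and 0 and 1 adjusted over the list alone. Cholangiocyte markers (1 measured), neutrophil markers (1), lymphocyte markers (2), erythroid markers (2) and pancreatic acinar markers (2) had 0 called, but for Epcam, the only cholangiocyte marker, Ighm and Hbb-b2 this says nothing about the cells. The neutrophil marker, Lcn2, differed by 3.02 ± 1.23 (adjusted p = 0.179) and rose adjusted over the list alone, a list of this 1 gene. The median and the mean of the change pointed opposite ways for bile acid synthesis and transport, Keap1-Nrf2 pathway regulators, early response transcription factors, the circadian clock, pericentral hepatocyte genes, hepatocyte markers and stellate cell and fibroblast markers. Of the 20 hepatocyte markers 1 rose, Tdo2 at 0.34 ± 0.07. This call was lost in 3 of 12 fits without 1 array (up to 0.0625, without WT vehicle replicate 1).

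To identify the hepatic genes altered by pharmacologic activation, WT livers 6 h after CDDO-Im were compared with WT livers after vehicle. Mt2 rose 37.6-fold, Mt1 rose by 4.32 ± 0.46 (log2 change ± SE), Nqo1 rose 10.9-fold (adjusted p = 9.34e-04) and Srxn1 8.4-fold (adjusted p = 4.77e-04). Bmp6, the ligand through which the liver senses iron, rose 5.7-fold (log2 change 2.51 ± 0.26, adjusted p = 9.34e-04) and the aldo-keto reductase Akr1b8 5.84-fold. The largest fall was that of Pnpla3, by -3.59 ± 0.32 (log2, SE), from 6.01 ± 0.24 to 2.42 ± 0.15, and Fasn fell from 14.33 ± 0.13 to 11.82 ± 0.57 (SD, n = 3).

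By limma 304 genes were called, of which 157 rose and 147 fell, and 303 of them had groups that did not overlap, as did 23.3% of all genes tested (chance gives 10%). Centring each array on its median turned the split to 228 that rose and 121 that fell, since 51.6% of the calls were rises before centring and 65.3% after. With quantile normalization 190 rose and 136 fell. Of the called genes 95 differed at least 2-fold. The other large rises were Cbr3 at 5.87 ± 0.88, Ddit4, an inhibitor of mTOR signalling, at 2.78 ± 0.63, Lyve1 at 2.57 ± 0.46 and Samd4 at 2.34 ± 0.35. Other large falls were those of Angptl8, a regulator of lipoprotein lipase, at -3.43 ± 0.68, the activin subunits Inhba and Inhbe at -2.79 ± 0.59 and -1.94 ± 0.41 and Tsc22d1 at -2.29 ± 0.20. Further falls were those of the elongase Elovl6 at -2.28 ± 0.41, Mid1ip1, an activator of acetyl-CoA carboxylase, at -2.13 ± 0.33, Aacs at -1.98 ± 0.46 and Srebf1, the sterol regulatory transcription factor of lipogenesis, at -1.97 ± 0.40. Without WT CDDO-Im replicate 4 the calls for Ddit4, Lyve1, Angptl8, Inhba, Elovl6, Aacs, Srebf1 and Inhbe ended and the count was 106. Each of these 8 calls was lost in at least 2 of 12 fits without 1 array, and those of Ddit4 and Aacs in 9. It was 163 without WT CDDO-Im replicate 3, 165 without WT vehicle replicate 2 and 187 without WT vehicle replicate 3.

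Glutathione synthesis and conjugation had 7 of 21 members that rose and 14 not called, or 12 that rose adjusted over the list alone (median 0.52, camera adjusted p = 1.72e-10, adjusted p = 0.137 with an estimated correlation). Without WT CDDO-Im replicate 4, 4 rose. Gsta2 rose 4.94-fold, Gclc 2.83-fold and Gclm by 1.07 ± 0.11 (adjusted p = 9.34e-04). Quinone, aldehyde and peroxide detoxification had 9 of 23 that rose, or 14 adjusted over the list alone (median 0.34, camera adjusted p = 2.32e-10, adjusted p = 0.286 with an estimated correlation), with Txnrd1 at 1.40 ± 0.13 and Cbr1 at 1.48 ± 0.16. Hmox1 rose by 1.47 ± 0.29 (adjusted p = 0.022). Glucuronidation and sulfation had 3 of 21 that rose, with the same count adjusted over the list alone (median 0.15, camera adjusted p = 0.00929, adjusted p = 0.286 with an estimated correlation), among them Ugdh at 1.15 ± 0.13, and 1 rose without WT CDDO-Im replicate 3 or 4. Hepatic transporters had 3 of 21 that rose, or 4 adjusted over the list alone (median 0.14, camera adjusted p = 0.0205, adjusted p = 0.89 with an estimated correlation), among them Abcc4 at 1.67 ± 0.28 and Abcc1 at 1.72 ± 0.27. Autophagy and ubiquitin adaptors had 1 of 20 that rose, the adaptor Sqstm1 at 0.57 ± 0.10, or 2 adjusted over the list alone (median 0.08, camera adjusted p = 0.0205, adjusted p = 0.61 with an estimated correlation). In WT livers given the drug, Keap1-Nrf2 pathway regulators were not called as a list (adjusted p = 0.214), but Mafg rose by 1.02 ± 0.09, the Nrf2 competitor Bach1 by 1.14 ± 0.14 and Keap1 as above. The calls for Hmox1 and Rpia were lost in 4 and 2 of 12 fits without 1 array (up to adjusted p = 0.0854 and 0.079, without WT CDDO-Im replicate 4) and those for Keap1 and Sqstm1 in 10 and 1 (up to 0.134 and 0.0509, without WT CDDO-Im replicate 3). The list calls ended for glucuronidation and sulfation without WT vehicle replicate 2 or WT CDDO-Im replicate 2 (adjusted p = 0.0872 and 0.0813), for hepatic transporters without WT vehicle replicate 3 or WT CDDO-Im replicate 4 (0.0878 and 0.0587), and for autophagy without WT CDDO-Im replicate 2 or 3 (0.0577 and 0.0537). NADPH production had 3 of 12 that rose and 1 that fell (adjusted p = 0.214), with Pgd at 1.01 ± 0.14 and Rpia at -1.62 ± 0.30.

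Fatty acid and triglyceride synthesis had 9 of 24 members that fell and 0 that rose, or 14 and 1 adjusted over the list alone (median -0.51, camera adjusted p = 1.17e-06, adjusted p = 0.47 with an estimated correlation). Pnpla3, Fasn, Elovl6 and Srebf1 were among the members that fell, and 5 fell without WT CDDO-Im replicate 3 or 4. Cholesterol synthesis and uptake was called as lower with 0 of 19 members called, also adjusted over the list alone (median -0.52, camera adjusted p = 0.0155, adjusted p = 0.933 with an estimated correlation). Its call ended without WT vehicle replicate 1, the liver with the high cholesterol genes (adjusted p = 0.473). Interferon response genes had 1 of 17 that fell, Oasl1 at -1.73 ± 0.38, and were not called as a list (adjusted p = 0.155). Among clock genes Bhlhe40 and Per2 fell, with log2 changes of -1.38 ± 0.27 and -1.23 ± 0.29, and the list was not called (adjusted p = 0.809). The calls for Oasl1, Bhlhe40 and Per2 were lost in 6, 4 and 9 of 12 fits without 1 array, with the highest adjusted p, 0.111, 0.0922 and 0.149, without WT CDDO-Im replicate 4.

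To ask how far the genetic and the pharmacologic responses overlapped, both were set against each other over the 8338 genes. In both, 78 genes rose and 49 fell, and 0 were called in opposite directions. Independent lists of these lengths would share 5.10 rises and 4.80 falls. Among the shared rises were Cbr3, Mt2, Mt1, Nqo1, Srxn1, Gsta2 and Abcc4, and among the shared falls Pnpla3, Fasn and Plin2. The log2 changes correlated across genes with r = 0.547, although genes are not independent replicates. Both responses were measured against the same 3 WT vehicle arrays, which correlates them with no effect at all. Groups simulated without any change gave a mean r of 0.450 (range -0.586 to 0.897 over 100 draws). The observed r lay inside this range. The draws gave 0 shared calls, but without any change there are few calls to share. That count therefore cannot show how shared controls act on real calls. The share of genes changing in the same direction in both responses was 65.2%. The simulated mean was 65.5% (range 28.1% to 86.5%), so this share showed no excess. The covariance was 0.0957 against a simulated 0.0212 (range -0.0204 to 0.0906), a difference of 0.0745. The 3 controls were too few to split, so part of the excess over independent lists may come from the shared controls. The count of 127 was 61 without WT CDDO-Im replicate 4, 77 without WT CDDO-Im replicate 3 and 84 without CKO vehicle replicate 3.

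**Figure D2:**
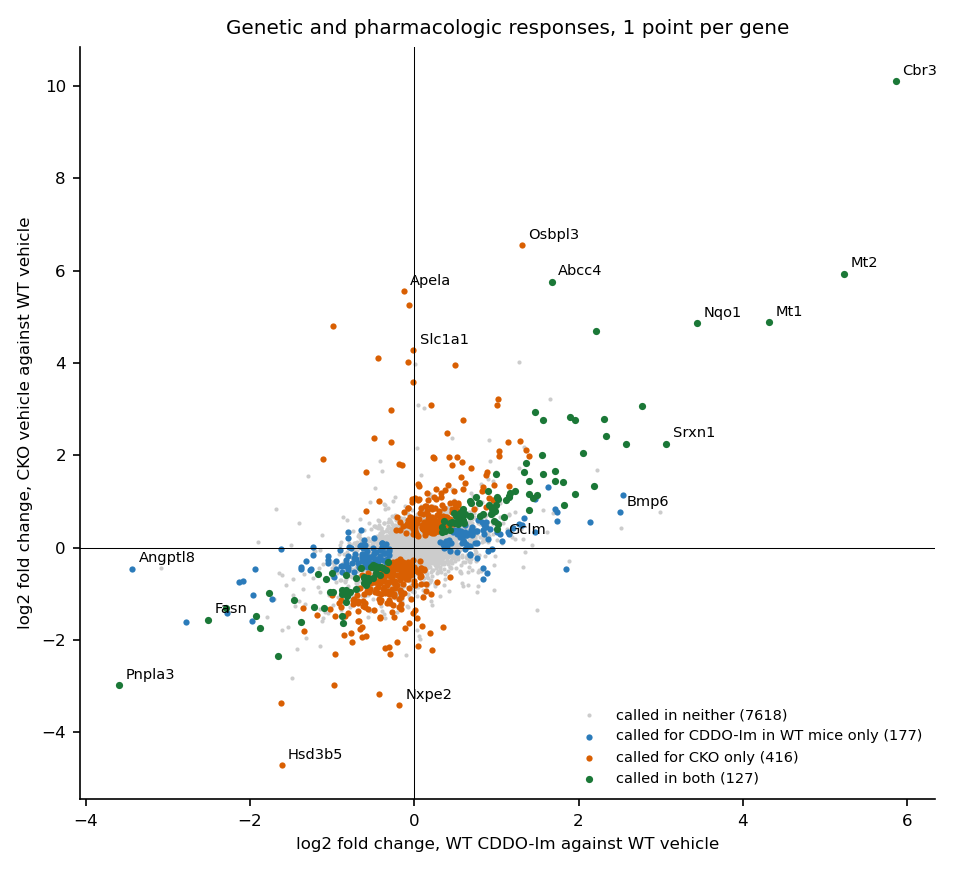
Log2 change of each of the 8338 genes in vehicle-treated CKO livers (vertical axis) against its log2 change after CDDO-Im in WT livers (horizontal axis), both relative to WT vehicle, with 1 point per gene coloured by the calls. The 127 genes called in both lie in the upper right and lower left parts, 416 were called in the CKO comparison alone and 177 in the drug comparison alone.

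To find where the responses differed, CKO vehicle livers were compared directly with WT CDDO-Im livers. The drug had acted for 6 h only, while the deletion was genetic, so duration cannot be told apart from the kind of activation. Anxa13 was higher in the knockout than after the drug by 5.79 ± 0.57, Apela by 5.69 ± 0.26, Slc22a12 by 5.32 ± 0.51 and the glutathione peroxidase Gpx2 by 4.56 ± 0.55 (log2 ± SE), the last from 4.41 ± 0.39 to 8.97 ± 0.26 (SD, n = 3). Abcc4 was 17-fold and Abcc5 11.1-fold higher (adjusted p = 8.09e-05 and 1.94e-04), and Nqo1 2.67-fold higher (adjusted p = 0.0497). Gclm and Bach1 were lower in the knockout than after the drug, by -0.92 ± 0.11 and -0.80 ± 0.14. Nxpe2 was lower by -3.24 ± 0.29 and Elovl3 by -2.73 ± 0.58.

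By limma 358 genes were called, 202 higher and 156 lower in CKO vehicle livers (196 and 196 with median centring), 357 of them with groups that did not overlap, as in 27.8% of all genes tested (chance gives 10%). Of the 127 genes called in both responses, 12 also differed here, 6 with the larger response in the knockout and 6 with the larger response to the drug. Further genes with large differences were Osbpl3 at 5.24 ± 0.43, Slc1a1 at 4.29 ± 0.24, Cbr3 at 4.24 ± 0.88, the serpin Serpinb1a at 4.10 ± 0.81 and Tinag at 3.59 ± 0.42. In the other direction they were Mn1 at -2.44, Slc35e3 at -2.30, Tmem19 at -2.17, the vasopressin receptor Avpr1a at -2.08, the growth factor binding protein Igfbp2 at -2.04, Gas1 at -2.02, Slco1a1 at -1.85 and Cadps2 at -1.85. The calls for Cbr3, Serpinb1a, Elovl3, Avpr1a, Igfbp2, Gas1 and Cadps2 each ended without at least 1 of the 6 arrays compared, with highest adjusted p values from 0.0509 for Cadps2 to 0.104 for Igfbp2. The calls for Nqo1 and Bach1 were lost in 10 and 3 of 12 fits without 1 array (up to 0.127 and 0.0696, without CKO vehicle replicate 3). The count was 108 without CKO vehicle replicate 3, 126 without WT CDDO-Im replicate 3, 182 without CKO vehicle replicate 4, 201 without WT CDDO-Im replicate 4 and 211 without WT CDDO-Im replicate 2.

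Interferon response genes were lower in CKO vehicle than in WT CDDO-Im livers, with 2 of 17 members called, or 10 adjusted over the list alone (median -0.73, camera adjusted p = 9.20e-06, adjusted p = 0.9 with an estimated correlation). These were Irf9 at -1.13 ± 0.20 and the immunity-related GTPase Iigp1 at -1.26 ± 0.31, and these calls were lost in 2 and 9 of 12 fits without 1 array, with the highest adjusted p, 0.0625 and 0.158, without CKO vehicle replicate 3. In WT CDDO-Im replicate 3, all 17 members lay above the mean of the other 2 livers of its group, by a median of 0.66. Male-biased liver genes were lower with 2 of 17 called, or 6 adjusted over the list alone (median -0.55, camera adjusted p = 0.00246, adjusted p = 0.929 with an estimated correlation), and the call ended without CKO vehicle replicate 4 (adjusted p = 0.0508). Cholesterol synthesis and uptake was called as lower with 0 of 19 members called, also adjusted over the list alone (median -0.28, camera adjusted p = 0.0455, adjusted p = 0.938 with an estimated correlation). That call ended without CKO vehicle replicate 4 (adjusted p = 0.365), WT CDDO-Im replicate 4 (0.15) or CKO CDDO-Im replicate 2 (0.0501). Glutathione synthesis and conjugation was not called (2 higher and 1 lower of 21, 3 and 3 adjusted over the list alone, adjusted p = 0.425). Quinone, aldehyde and peroxide detoxification was not called either (5 higher and 0 lower of 23, 5 and 4 adjusted over the list alone), and its median of -0.05, mean of 0.18 and downward test (adjusted p = 0.941) differed in sign. Its 5 were 1 without CKO vehicle replicate 3 or 4 or WT CDDO-Im replicate 2 or 3, and 3 without CKO CDDO-Im replicate 4 or WT CDDO-Im replicate 4. The signs differed for fatty acid and triglyceride synthesis too, with a median of 0.25, a mean of -0.11 and an adjusted p of 0.941. Of its 24 members 1 was higher and 3 lower, or 4 and 6 adjusted over the list alone. The 3 were 1 without CKO vehicle replicate 3 and 0 without CKO vehicle replicate 4 or WT CDDO-Im replicate 3 or 4. In it Agpat2 was higher by 0.62 ± 0.12 and Fads1 lower by -1.35 ± 0.28, both calls lost in 4 of 12 fits without 1 array (up to 0.0974 and 0.101, without CKO vehicle replicate 3).

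To test whether CDDO-Im acted further in CKO livers, CKO mice given the drug were compared with CKO mice given vehicle. Nrf2 target genes differed between these groups by amounts that did not pass the test. Nqo1 was 11.08 ± 0.07 after vehicle and 10.85 ± 0.17 after CDDO-Im (log2 signal, SD, n = 3), a difference of -0.23 ± 0.35 (SE). Gclc differed by -0.05 ± 0.11, Txnrd1 by -0.08 ± 0.13, Gclm by 0.27 ± 0.11 and Hmox1 by -0.32 ± 0.29, with adjusted p from 0.515 for Gclm to 0.918 for Gclc. By limma 0 of the 8338 genes were called, and 790 had an unadjusted p under 0.05. Groups did not overlap in 14.6% of the genes, where chance gives 10%. The smallest adjusted p was 0.225, which several genes shared, among them Bmp6 and the AMP deaminase Ampd3, the latter chosen after its values were seen. The signal of Ampd3 was 3.66 ± 0.24 after vehicle and 5.07 ± 0.51 after the drug, against 3.11 ± 0.35 and 5.24 ± 0.22 in the WT groups. Differences among list members, none of which passed the test, included -3.36 ± 0.75 for the steroid hydroxylase Cyp17a1 (adjusted p = 0.294), 2.68 ± 0.83 for Igfbp1 and -2.06 ± 1.23 for the acute phase protein Lcn2. They also included 1.81 ± 0.54 for Pck1, an enzyme of gluconeogenesis, 1.69 ± 0.46 for Lyve1 and 1.65 ± 0.41 for Akr1b8.

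Camera called 7 lists between the CKO groups although 0 of their members were called, over all genes or adjusted over the list alone. Heat shock and chaperones (median -0.32 over 20 genes, camera adjusted p = 5.83e-04, adjusted p = 0.933 with an estimated correlation) and the unfolded protein response and amino acid stress (median -0.23 over 28 genes, camera adjusted p = 0.00414, adjusted p = 0.924 with an estimated correlation) were lower after the drug. Proteasome subunits were lower too (median -0.16 over 34 genes, camera adjusted p = 3.58e-04, adjusted p = 0.933 with an estimated correlation). The largest differences among heat shock and proteasome members were -1.24 ± 0.63 for the chaperone Hspa1b and -0.29 ± 0.12 for the proteasome subunit Psmd4. Fatty acid oxidation and PPAR alpha targets (median 0.12, camera adjusted p = 0.00424, adjusted p = 0.934 with an estimated correlation) and carboxylesterases (median 0.33 over 8 genes, camera adjusted p = 0.04, adjusted p = 0.929 with an estimated correlation) were higher. The hormone Fgf21, a member of the fatty acid oxidation list, went against its list's direction, at -1.68 ± 0.75. Cytochrome P450s of xenobiotic metabolism (median 0.12 over 24 genes, camera adjusted p = 0.0274, adjusted p = 0.933 with an estimated correlation) and the cell cycle (median 0.33 over 12 genes, camera adjusted p = 0.04, adjusted p = 0.884 with an estimated correlation) were higher as well. Of these 7, only the proteasome call held without each of the 12 arrays in turn. The call ended for heat shock without CKO CDDO-Im replicate 2 (adjusted p = 0.0547), for the unfolded protein response without CKO vehicle replicate 5 (0.0541) and for fatty acid oxidation without CKO vehicle replicate 5 (0.166) or CKO CDDO-Im replicate 3 or 4 (0.0866 and 0.0611). For cytochrome P450s it ended without CKO vehicle replicate 3 or 5 or CKO CDDO-Im replicate 2 or 3 (0.0801 to 0.368). For the cell cycle it ended without CKO vehicle replicate 5, CKO CDDO-Im replicate 3 or 4 or WT vehicle replicate 2 (0.0711 to 0.468), and for carboxylesterases without CKO vehicle replicate 3 or 5, any CKO CDDO-Im array or WT vehicle replicate 2 (0.0524 to 0.25). In CKO CDDO-Im replicate 2 all 27 acute phase genes lay above the mean of the other 2 livers, by a median of 0.59.

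**Figure D3:**
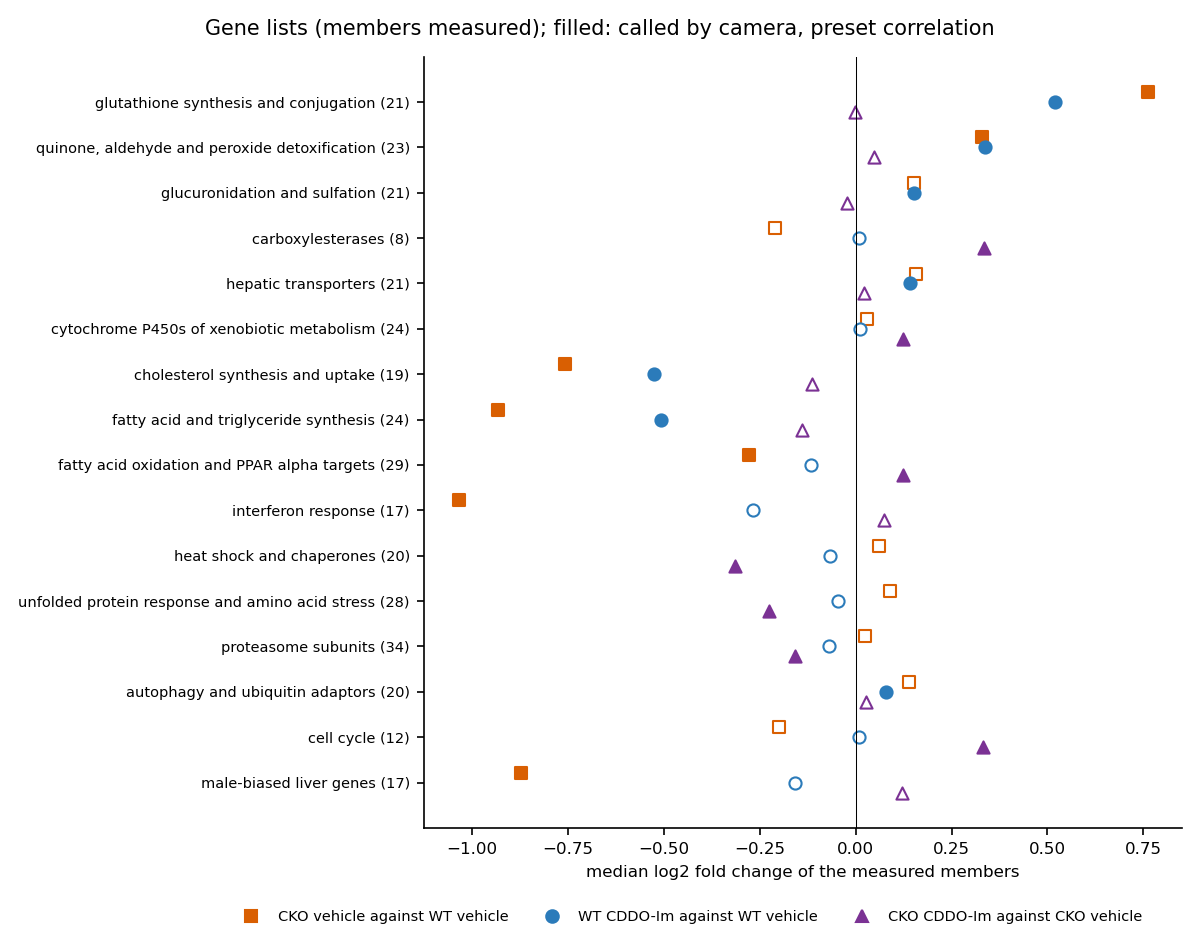
Median log2 change of the measured members of a gene list (horizontal axis) in 3 comparisons, for the 16 lists called by camera in at least 1 of them, with filled points where the list was called at the preset correlation. All these calls are lost with an estimated correlation. Glutathione synthesis and conjugation lies at 0.76 in CKO vehicle and 0.52 in WT CDDO-Im livers relative to WT vehicle, and fatty acid and triglyceride synthesis at -0.93 and -0.51.

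To compare the genotypes under the drug, CKO CDDO-Im livers were set against WT CDDO-Im livers. Anxa13 was higher in CKO livers (8.80 ± 0.35 against 2.60 ± 0.40, log2 signal, SD, n = 3), Osbpl3 by 5.28 ± 0.43, Gpx2 by 4.84 ± 0.55, Slc1a1 by 4.61 ± 0.24, Apela by 4.47 ± 0.26 and Abcc4 by 3.96 ± 0.28 (log2 ± SE). Srxn1 was lower by -1.33 ± 0.25 (adjusted p = 0.0341) and Gclm by -0.65 ± 0.11 (adjusted p = 0.0224), and Nqo1 differed by 1.19 ± 0.35 without passing the test (adjusted p = 0.125). The largest falls were Nxpe2 at -3.98, Avpr1a at -2.53, Mn1 at -2.28, Slc35e3 at -2.21, Spsb4 at -2.09, Gas1 at -2.06, Cadps2 at -2.05, Tmem19 at -2.05 and the sulfotransferase Sult5a1 at -1.61. Other large rises were Slc22a12 at 4.33, Tafa2 at 4.30, Tinag at 3.52 and Serpinb1a, with a mean signal of 9.50 against 5.30. By limma 128 genes were called, 62 higher and 66 lower (78 and 67 with median centring), and the groups of all 128 did not overlap, as in 22.7% of all genes tested (chance gives 10%). Of the 543 genes called between genotypes under vehicle, 35 were also higher and 24 also lower here, against 2.02 and 2.15 for independent lists. The groups of these 2 comparisons share no array, but both tests use the same estimate of each gene's spread, so their calls are not independent.

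Interferon response genes were lower in CKO than in WT livers under the drug as well, with 1 of 17 called, Irf9 at -1.14 ± 0.20, or 4 adjusted over the list alone (median -0.59, camera adjusted p = 2.32e-04, adjusted p = 0.924 with an estimated correlation). Cholesterol synthesis and uptake was lower with 0 of 19 called, also adjusted over the list alone (median -0.38, camera adjusted p = 0.0131, adjusted p = 0.933 with an estimated correlation), a call that ended without CKO CDDO-Im replicate 3 (adjusted p = 0.0507) or WT CDDO-Im replicate 4 (0.0587). Glutathione synthesis and conjugation (2 higher and 1 lower of 21, 4 and 2 adjusted over the list alone, adjusted p = 0.121) and quinone, aldehyde and peroxide detoxification (2 and 1 of 23, 5 and 1 adjusted over the list alone, adjusted p = 0.277) were not called. The count of 128 was 32 without WT CDDO-Im replicate 3, 34, 41 and 48 without CKO CDDO-Im replicates 3, 4 and 2, and 63 and 76 without WT CDDO-Im replicates 2 and 4. The calls for Tafa2, Serpinb1a, Avpr1a, Slc35e3, Spsb4, Gas1, Cadps2 and Sult5a1 each ended without at least 1 array, with highest adjusted p values from 0.0521 for Spsb4 to 0.14 for Gas1. The call for Srxn1 was lost in 8 of 12 fits without 1 array (up to 0.134, without WT CDDO-Im replicate 3) and those for Gclm and Irf9 in 4 each (up to 0.0852 and 0.0857, without CKO CDDO-Im replicate 3).

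To test whether the drug effect itself depended on genotype, the interaction was fitted across the 4 groups. Srxn1, Gclc, Mt2, Mt1 and Nqo1 rose with CDDO-Im in WT livers and not to the same extent in CKO livers. The drug effect on Srxn1 was 3.07 in WT and -0.52 in CKO livers, a difference of -3.59 ± 0.36 (log2 ± SE, adjusted p = 0.0052), and that on Gclc differed by -1.54 ± 0.15 (adjusted p = 0.0052). Mt2 (5.23 in WT and 0.61 in CKO, difference -4.62 ± 0.78), Mt1 (4.32 and 0.29, difference -4.03 ± 0.65) and Nqo1 (3.45 and -0.23, difference -3.68 ± 0.49) went the same way. Tsc22d1 fell in WT livers by more than in CKO livers, with a difference of 1.70 ± 0.29. Pnpla3 was called too (3.02 ± 0.46), but its signals in CKO vehicle livers, 2.55, 4.01 and 2.55, lay near the lowest value, so a fall as large as in WT livers could not have been measured there. Its value does not show that the drug effect differed.

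By limma the interaction was called for 23 genes, of which 2 had a positive and 21 a negative value, and 858 genes had an unadjusted p under 0.05. The others named by rule were Gsta2 at -2.15, Ppfibp2 at -2.05, the aldo-keto reductase Akr1c19 at -1.66 and Pir at -1.55. They went on with Cbr1 at -1.50, Txnrd1 at -1.48, Pgd at -1.22, Ugdh at -1.19 and Mafg at -0.98, with adjusted p from 0.0138 for Txnrd1 to 0.0424 for Akr1c19. Gclm (-0.80 ± 0.16, adjusted p = 0.0885) and Hmox1 (-1.79 ± 0.40, adjusted p = 0.136) did not pass the interaction test. Srxn1 and Gclc kept their calls without each of the 12 arrays in turn, and the other genes named here each lost theirs in 2 to 11 of the 12 fits, with highest adjusted p values from 0.0561 for Ppfibp2 to 0.135 for Mt2. The count of 23 was 2 without CKO CDDO-Im replicate 2, 3 without CKO CDDO-Im replicate 3 or CKO vehicle replicate 3, and 8 to 14 without WT CDDO-Im replicate 4, 3 or 2, CKO vehicle replicate 5 or 4, CKO CDDO-Im replicate 4 or WT vehicle replicate 1.

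Glutathione synthesis and conjugation had 3 of 21 members with a negative interaction, or 11 adjusted over the list alone (median -0.55, camera adjusted p = 1.21e-08, adjusted p = 0.174 with an estimated correlation), and quinone, aldehyde and peroxide detoxification had 4 of 23, or 7 adjusted over the list alone (median -0.20, camera adjusted p = 8.44e-07, adjusted p = 0.47 with an estimated correlation). The 3 were 1 without CKO CDDO-Im replicate 2 or 3. The 4 were 1 without CKO vehicle replicate 3 or CKO CDDO-Im replicate 2 or 3 and 2 without CKO vehicle replicate 4 or 5 or WT CDDO-Im replicate 2 or 4. Fatty acid and triglyceride synthesis had 1 of 24 with a positive interaction, Pnpla3, which as said lay near the lowest value in CKO livers, or 3 adjusted over the list alone (median 0.45, camera adjusted p = 4.12e-06, adjusted p = 0.492 with an estimated correlation). Fatty acid oxidation and PPAR alpha targets had 0 of 29 called, or 2 positive adjusted over the list alone (median 0.29, camera adjusted p = 0.00246, adjusted p = 0.933 with an estimated correlation), and interferon response genes 0 of 17, or 2 positive adjusted over the list alone (median 0.45, camera adjusted p = 0.018, adjusted p = 0.933 with an estimated correlation). Heat shock and chaperones had 0 called (median -0.28, camera adjusted p = 0.0205, adjusted p = 0.938 with an estimated correlation), as had hepatocyte markers (median -0.08, camera adjusted p = 0.04, adjusted p = 0.52 with an estimated correlation), of whose 20 measured genes 3 were in another list. The call of fatty acid oxidation ended without WT vehicle replicate 2 or WT CDDO-Im replicate 2 (adjusted p = 0.0872 and 0.0813), and that of interferon response without CKO vehicle replicate 3, CKO CDDO-Im replicate 2 or WT CDDO-Im replicate 2 or 4 (0.0638 to 0.178). That of heat shock ended without any of 6 arrays (up to 0.235, without WT vehicle replicate 1) and that of hepatocyte markers without any of 9 arrays (up to 0.107, without WT CDDO-Im replicate 2) and with genes of repeated values left out (0.0666).

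**Figure D4:**
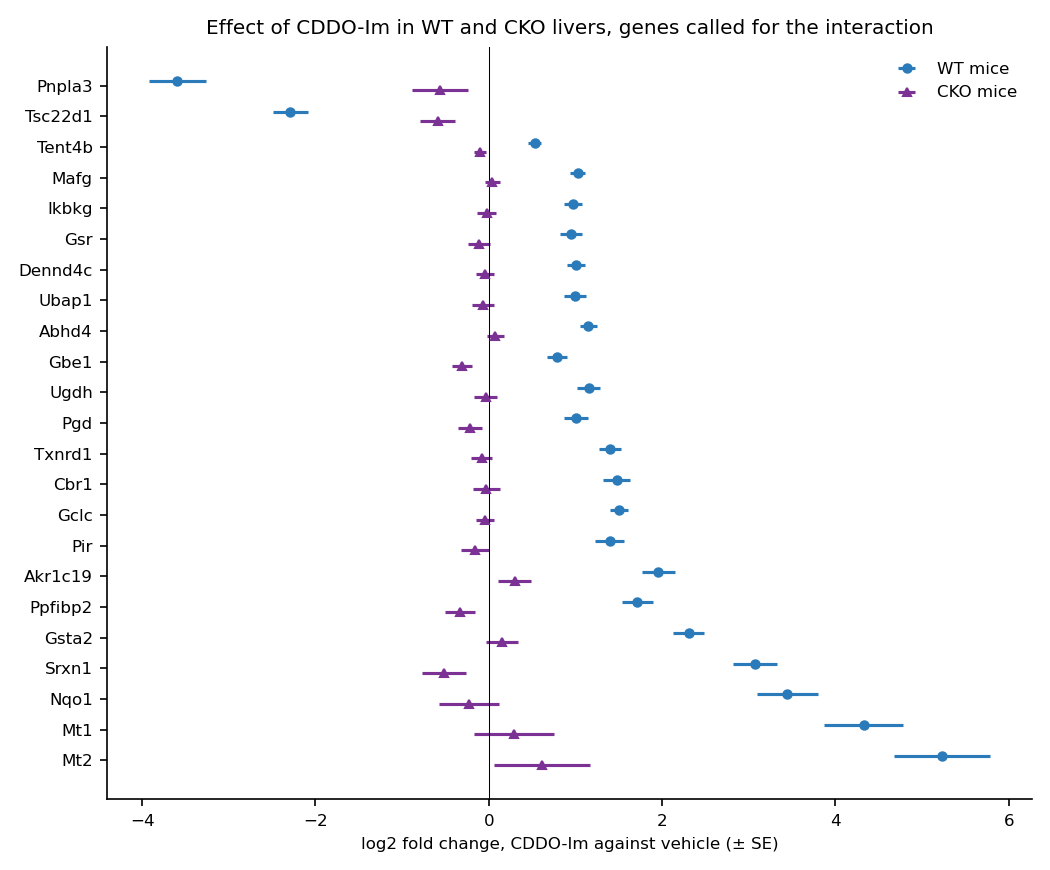
Log2 change with CDDO-Im in WT livers and in CKO livers for the 23 genes called in the interaction test, with points for the estimates, bars for ± 1 SE (n = 3 livers per group) and a line at 0. Mt2 lies at 5.23 in WT and 0.61 in CKO livers, and Srxn1 at 3.07 and -0.52. Pnpla3, at -3.59 and -0.57, lay near the lowest signal in CKO vehicle livers.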

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

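Some tests were chosen only after the results they bear on were seen. These tested lost power, a response already at its limit, clusters over the whole gene order, macrophage number and single arrays. In all, 13 tests of explanations were run.

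A direct test of the difference called 23 genes for an effect of CDDO-Im that differed between WT and CKO livers (limma, interaction at an adjusted p under 0.05). For Pnpla3, 1 of them (3.02, log2), the test is void, since its CKO vehicle signals (2.55, 4.01 and 2.55) lay near the lowest value. The interaction values (log2, CKO drug effect minus WT drug effect) were 1.70 for Tsc22d1, -4.62 for Mt2, -4.03 for Mt1, -3.68 for Nqo1 and -3.59 for Srxn1. They were -2.15 for Gsta2, -2.05 for Ppfibp2, -1.66 for Akr1c19, -1.55 for Pir, -1.54 for Gclc, -1.50 for Cbr1, -1.48 for Txnrd1, -1.22 for Pgd, -1.19 for Ugdh and -0.98 for Mafg. The same test by camera marked 7 lists, with median interactions of -0.55 for glutathione synthesis and conjugation, -0.20 for quinone, aldehyde and peroxide detoxification, 0.45 for fatty acid and triglyceride synthesis, 0.29 for fatty acid oxidation and PPAR alpha targets, 0.45 for interferon response, -0.28 for heat shock and chaperones and -0.076 for hepatocyte markers. None of the 7 was called with an estimated correlation. When the 12 arrays were regrouped after the additive effects were removed, 1 of 100 splits, the real one, called 23 genes or more and the highest other called 1. Chance is argued against for this count, but not for each gene, and the count was 2 without CKO CDDO-Im replicate 2. The regrouped arrays keep the interaction signal in their spread, which lowers their counts, so the gap overstates the contrast.

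The first pattern is that 0 genes were called for the drug in CKO livers (790 at an unadjusted p under 0.05, limma) against 304 in WT livers. A larger spread among CKO arrays over all tested genes is argued against, since the median variance per gene in CKO groups was 0.930 times that in WT groups (0.770 to 1.08 without any 1 array). The spread of the 304 genes alone was not compared, so a larger spread in them stays open. A response as large as in WT livers but missed for lack of power is also argued against for the 304 genes as a set. For single genes it stays open. Over the 304 genes the median drug effect in CKO livers was 0.153 times that in WT livers (95% bootstrap interval over genes 0.113 to 0.218). Selection inflates the WT effects. In CKO livers 220 of the 304 genes (72.4%) changed in the WT direction, so a smaller response missed for lack of power stays open. Intervals here and below resample genes and not livers, so they leave out the spread between animals. A limit already reached in CKO livers may account for it and cannot be told apart from other genotype differences, since genes already shifted there responded less by 0.204 (log2, interval 0.129 to 0.314) when classed by CKO vehicle arrays but more when classed by CKO CDDO-Im arrays (difference -0.164, interval -0.231 to -0.068), and the arrays each classing shares with the effect bias it in opposite directions. The criterion first written for this test, a difference at or below 0 under either classing, would have counted against the limit, and it was changed to both classings after the values were seen, so the test is read as deciding nothing.

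The second pattern is the lower interferon response list in CKO livers. Fewer macrophages is argued against as the cause, as far as marker RNA tracks cell number. Over all CKO against all WT arrays the median of the 13 macrophage and Kupffer cell markers was 0.194 (log2, interval over genes 0.060 to 0.341). Whole-liver RNA does not tell cell number from expression per cell. Ccr2, 1 of the 13, held a value repeated on 8 arrays. The median of the interferon list was -0.744, with 17 of 17 genes lower. A single array is argued against as the cause of the list's call between the vehicle groups, which was lost in 0 of 12 fits without 1 array (highest adjusted p = 3.29e-07). An effect of Keap1 loss and a difference between the animals in earlier exposure or housing stay open and were not tested. The list's call is lost with an estimated correlation (adjusted p = 0.61).

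The third pattern is the set of 59 genes called for genotype both under vehicle and under the drug. A segment of other strain origin around the targeted Keap1 locus was tested as their source. Of the 40 tested genes nearest Keap1 in gene order, 1 (Col5a3, named here after its values were seen) was among the 59. Random sets of 40 held 0.277 on average and 1 at their 95th percentile. These neighbours account for few of the 59, but with so few expected the test cannot decide whether such a segment is there. Clusters over the whole gene order were not shown either. The most such genes in 20 neighbouring tested genes was 3 (Nt5e, Pls1 and Spsb4, which share a chromosome). Whether that chromosome is the one that holds Keap1 was not examined. A segment reaching further from Keap1 than its 40 nearest genes was not tested. This number was reached by 3307 of 10000 shuffles of gene order and equals their 95th percentile of 3. A count inside the range of the shuffles does not exclude linked segments. Segments holding 1 or more of these genes stay open.

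For the comparisons of 3 arrays with 3, the 10 splits of the 6 arrays are too few for a share under 0.05. CKO vehicle against WT vehicle called 543 genes in the real split (1 of 10 splits as large) and 1 in the highest other, and WT CDDO-Im against WT vehicle called 304 (1 of 10) and 1. CKO vehicle against WT CDDO-Im called 358 (1 of 10) and 0, CKO CDDO-Im against WT CDDO-Im 128 (1 of 10) and 0, and CKO CDDO-Im against CKO vehicle 0, as did all 10 splits.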

How the results depend on the processing

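Leaving out WT vehicle replicate 1 and CKO vehicle replicate 3 together, and leaving out the 421 genes with a repeated value, were chosen after seeing the data, and the other alternatives were planned. Over 376 single-gene results, 0 that were called with or without a setting changed direction under the settings run for them, which were not the 2 groups alone or the 1.5-fold minimum and covered 301 of them with plain _at probe sets, 341 with the stricter filter and 369 with genes of repeated values left out. The largest losses of calls were 125 under the replicate block, 113 with no filter on low values and 98 without both of those arrays, and of 4512 gene results without 1 array 588 lost and 18 gained a call. Quantile normalization, median centring, trended and robust variance, array weights, every probe set, plain _at probe sets and leaving out repeated values each ended at most 8. Of the 33 list calls, 33 were lost with an estimated correlation, 7 under the block, 7 under quantile normalization, 8 with plain _at probe sets, 6 without both arrays, 3 with the stricter filter, 2 with median centring, 1 with no filter and 1 with repeated values left out, and 55 of 396 without 1 array. Apart from the estimated correlation, the calls of glutathione, quinone and fatty acid synthesis lists in the CKO, drug and interaction tests, of interferon genes in all 3 comparisons of CKO with WT livers, of cholesterol and male-biased genes between the vehicle groups and of proteasome subunits between the CKO groups held under every setting run. Signal over background limits what was seen, since 16494 to 16776 probe sets per array lay at the floor, where no fall can be measured.

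Genes called, in the order CKO vehicle against WT vehicle, WT CDDO-Im against WT vehicle, CKO vehicle against WT CDDO-Im, CKO CDDO-Im against CKO vehicle, CKO CDDO-Im against WT CDDO-Im and interaction, were 543, 304, 358, 0, 128 and 23. With no filter on low values they were 232, 124, 119, 1, 29 and 7, with 55 in place of 127 shared by both responses and 218 of the 232 among the 543. With every probe set tested, where a gene can be counted more than once, 885 were called between the vehicle groups, 570 for the drug in WT livers, 215 between the drug groups and 48 in the interaction. With only the 2 groups compared, which leaves fewer residual degrees of freedom, the first 3 counts were 223, 85 and 112, and that between the drug groups was 56. Array weights gave 874 for CKO vehicle against WT CDDO-Im, 274 between the drug groups and 45 in the interaction. Plain _at probe sets gave 11 in the interaction, and the 1.5-fold minimum, which can only remove genes, gave 233 for CKO vehicle against WT CDDO-Im. Without both arrays they were 123, 163, 81, 0, 71 and 5, with 45 shared, and 115 of the 123 were among the 543. Except where the construction of the setting shows it, the cause was not tested.

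Without 1 array, the counts ranged from 275 to 537, 106 to 318, 108 to 379, 0 to 1, 32 to 139 and 2 to 31, the shared genes from 61 to 116 and the correlation of the responses from 0.491 to 0.591. The 1 gene called between the CKO groups came without CKO vehicle replicate 5. The arrays that moved a count of all called genes, or 1 of 3 or more list members, by over 1.5 times stand beside it in the results. Of the 84 counts of 1 or 2 list members 74 moved that far without at least 1 array, as did 10 of the 22 larger ones.

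The same replicate numbers occur in several groups. With the replicate block the counts were 55, 114, 150, 2, 42 and 3, and 51 of the 55 were among the 543. The vehicle groups share only replicate number 3, and the block uses up residual degrees of freedom. A lower count between them is therefore partly built into this setting and does not by itself show a batch. The deviations of the 12 same-number pairs of arrays correlated at -0.166 to 0.146 (median 0.060, against 0.007 for other pairs), and all 3 pairs between the drug groups and the only pair between the vehicle groups were positive (0.078 to 0.146), while those of CKO vehicle arrays with drug-treated arrays were all negative, so the numbers were not taken to pair the samples.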

Other observations

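The values below come from the planned fit, no explanation of them was tested, and which gene groups to describe here was chosen after they were seen.

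The iron exporter Slc40a1 rose in CKO vehicle livers by 0.65 ± 0.09 and with CDDO-Im in WT livers by 0.56 ± 0.09 (log2 change against WT vehicle ± SE, limma), and the zinc importer Slc39a4 was higher in CKO livers by 0.51 ± 0.13 under vehicle and 0.84 ± 0.13 under the drug. Bmp6 stood at 6.04 ± 0.44 in WT vehicle, 8.55 ± 0.07 in WT CDDO-Im, 6.80 ± 0.42 in CKO vehicle and 8.37 ± 0.37 in CKO CDDO-Im livers (log2 signal, SD, n = 3). Its drug effect in CKO livers, 1.57 ± 0.26, did not pass the test (adjusted p = 0.225), nor did the interaction (-0.94 ± 0.37, adjusted p = 0.433). Akr1b8 stood at 6.53 ± 0.90, 9.07 ± 0.04, 7.67 ± 0.52 and 9.32 ± 0.44 in the same order, with an interaction of -0.89 ± 0.58 (adjusted p = 0.644), so neither gene is shown to differ between genotypes in its drug effect.

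Among early response transcription factors Myc rose by 1.24 ± 0.25 in CKO vehicle livers and by 1.23 ± 0.25 with the drug in WT livers, while Jund fell in both (-0.81 ± 0.10 and -0.59 ± 0.10) and Jun fell in CKO vehicle livers (-1.49 ± 0.30). Ddit4 rose 8.35-fold in CKO vehicle livers and 6.85-fold with the drug, and the chaperone Dnajb9 was higher in CKO vehicle livers by 0.90 ± 0.18. Of the carboxylesterases, Ces1g rose by 1.98 ± 0.48 and Ces1f changed by -0.65 ± 0.15 in CKO vehicle livers. The proteasome subunit Psmb5 rose by 0.56 ± 0.12 there and the autophagy genes Map1lc3b and Ulk1 changed by 0.58 ± 0.13 and -0.98 ± 0.26, while their lists were not called in that comparison (camera adjusted p = 0.728 and 0.155). Without CKO vehicle replicate 3 all 5 of these carboxylesterase, proteasome and autophagy calls ended (adjusted p from 0.0836 for Ces1g to 0.13 for Ulk1), and the 5 were lost in 4 to 10 of 12 fits without 1 array, up to 0.147 for Ulk1 without WT vehicle replicate 1. Also lost without 1 array were the calls for Myc in CKO vehicle livers (4 of 12, up to 0.07) and after the drug (5, up to 0.087), Jun (4, up to 0.0631), Ddit4 in CKO vehicle livers (3, up to 0.0765) and after the drug (9, up to 0.134), Dnajb9 (1, 0.0528), Jund after the drug (1, 0.0512) and Slc39a4 under the drug (1, 0.0632). In bile acid synthesis the oxysterol hydroxylase Cyp39a1 rose by 1.85 ± 0.32. The 2 responses that share no array, the drug effect in WT and in CKO livers, correlated across the 8338 genes with r = 0.293 (Spearman 0.224), and the genotype effect under vehicle and under the drug with r = 0.609 (Spearman 0.394), where genes are not independent replicates. In CKO vehicle livers 81 genes were higher and 57 lower than in both WT groups, and in WT CDDO-Im livers 31 were higher and 31 lower than in both vehicle groups, counting genes called in both comparisons.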
